A study of Mus musculus with 30 samples.

How the data were processed

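The deposited files held whole-number counts of read pairs per gene for 30 thyroid libraries of C57BL/6 mice, 3 in each of 10 groups. The group of each library was taken from its title: FAD4T or wild type, male or female, 2 or 8 months, and for the ageing set wild-type males of 2 or 18 months. Wild-type male libraries of 2 months carry the title numbers 1 to 6. Numbers 1 to 3 were taken as the group beside the FAD4T males and numbers 4 to 6 as the group beside the 18-month males, since the series design lists the ageing set apart. Poly(A) RNA was purified from total RNA, and libraries were made with the dUTP method, which keeps the strand, and sequenced as paired ends, per the labels' protocols. The counts were made by the authors with featureCounts 1.6.0, per the file headers, from read pairs over exons grouped by gene, on the Ensembl release 88 annotation of GRCm38, from alignment files named for STAR, and with no strand option. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2, edgeR and the build GRCm39, which differ from the headers. Coordinates given are those in the count files. Counting without strand assigns reads of overlapping and antisense genes ambiguously, and genes with near-identical copies share reads, so such genes are uncertain. The normalised values behind the authors' own comparisons were not used here.

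Of 50686 genes in the files, 50376 identifiers had a symbol in the reference annotation and 310 did not, the latter taking at most 0.094% of a library's counts. Every count belonged to a named gene. Totals were 14083958 to 20256049 counts per library. Libraries of one group were compared before averaging, and 0 pairs were identical. All tests ran on the deposited counts in R 4.3.3 with edgeR 4.0.16: TMM normalisation, filterByExpr by group with a minimum count of 10, glmQLFit with robust estimation, glmQLFTest and Benjamini-Hochberg adjustment at 0.05, with a prior count of 0.125 for fold changes. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F. CPM values are relative to the TMM-scaled library total. The 24 libraries of the FAD4T set were fitted in 1 model with a mean per group (18493 genes, 16 residual degrees of freedom, common biological coefficient of variation 0.3). The 6 libraries of the ageing comparison were fitted apart (16283 genes, 4 residual degrees of freedom, coefficient 0.27). The 5 primary comparisons were FAD4T against wild type in each sex and age and 18 against 2 months. The 4 secondary ones were 8 against 2 months in wild-type males and females and male against female at 2 and 8 months, and 4 interactions tested how the FAD4T effect differed between sexes or ages.

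Before the data were examined, 31 gene lists of pathways and cell types with 467 members were fixed, of which 466 matched a gene. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, again with the correlation estimated from the data, and with fry, and 29 lists could be tested in the ageing comparison. Fry asks whether the genes of a list move, on balance, one way. The level of a list in a library is the mean of log2(CPM + 1) over its members. The genes named were set by a rule fixed then too. It took up to 10 rises and 10 falls per primary comparison and 4 of each per secondary comparison, the largest with adjusted p under 0.05, at least 5 CPM in 1 group and groups that did not overlap, leaving out unnamed gene models, pseudogenes and receptor segments. Where none passed, it took the 3 smallest p in each direction as values. It also took 4 genes often used in Alzheimer's models, 6 thyroid genes and up to 4 members of each called list. Of these the report names the ones it describes, and some are not reported here. CPM per comparison were scaled within its fit, and those of levels, sex-linked and organ genes over all 30 libraries. Organ genes of liver, kidney, heart, lung and thymic epithelium were listed after the first results were seen.

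The code was tested on simulated counts drawn from the real means and library sizes. Each gene was drawn independently around 1 mean over the libraries, so tissue differences between libraries of a group were not simulated. The rates below test the code and need not hold for the real comparisons. In the design of the males of 2 months, edgeR recovered 54% of 100 genes changed 2-fold and 80% of 100 changed 4-fold, over 18057 genes, with 11 false calls of 154. In the ageing design it recovered 40% and 86.9% of 100 and 99 genes over 16024, with 16 false calls of 149. DESeq2 made 26 false calls of 184 and 46 of 192 on the same counts. With no gene changed edgeR called 0 of 18107 and 0 of 16015, and DESeq2 was not run on those counts. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a fit of the compared groups alone, the title number as a block, 1 surrogate variable (sva 3.50.0), X and Y genes left out, other 2-month libraries as the young group and each library left out in turn. Marker levels as covariates, scaling by library totals and leaving out libraries of high thymocyte level were chosen after seeing the data. Tables and plots were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

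Title numbers 1 to 3 recur in each group of the FAD4T set, and the labels do not say what a number shares. In the FAD4T and wild-type males of 8 months, libraries of the same number deviated from their group means together (r = 0.29, 0.32 and 0.40 across genes, and all 6 libraries correlated best with their own number), so the numbers were taken to pair these libraries. In the other comparisons checked 0 to 3 of 6 did so. The pairing is thus an assumption, picked from several comparisons, and may be chance. With the number as a block, edgeR called 0 genes there, as without it.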

Results

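Thyroids of C57BL/6 mice were profiled by poly(A) RNA sequencing, and the counts per gene of 30 libraries fell into 10 groups of 3. In 8 of the groups, FAD4T and wild-type mice were compared at 2 and 8 months of age, males and females apart. The remaining groups were wild-type males of 18 months and a second set of 2-month wild-type males, numbered 4 to 6. The groups ask how thyroid transcripts differ with the FAD4T genotype, between a young and an old gland, and between the sexes. The labels do not say what the name FAD4T stands for or what these mice carry. The series design counts 3 mice per group and says nothing of litters or days of dissection, so the p-values measure the spread between these mice. Each library held 14083958 to 20256049 counts assigned to genes. Tg, the gene of thyroglobulin, on which thyroid hormone is made, took 4.64% to 27.0% of them. Levels are CPM, normalised counts relative to the library total, as mean ± SD of n = 3 libraries per group. Log2 fold changes carry their standard error (SE), and coordinates are those of GRCm38. "Rose" and "fell" are kept for genes that passed edgeR's test and for gene lists that passed camera's, which sets a list against all other genes with a preset correlation between its members. Of 135 list calls by camera over the 13 comparisons, 2 held with an estimated correlation, so that adjusted p stands beside each list.

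The transcripts of sex-linked genes matched the labelled sex in all 30 libraries. With CPM scaled over all libraries, Xist, the X-inactivation RNA, lay at 389 to 1290 CPM in females and 0.965 to 7.71 CPM in males, and the Y-linked Ddx3y lay at 45.6 to 98.8 CPM in males and at 3.26 CPM or less in females. App (ENSMUSG00000022892, chromosome 16, 84954440 to 85173707), the amyloid precursor gene, lay at 464 to 1300 CPM over the 30 libraries. Of App, Thy1 and Prnp, genes often used in mouse models of Alzheimer's disease, none passed in any of the 4 FAD4T comparisons, with adjusted p from 0.185 to 1. The exception was Thy1, which passed in females of 2 months without FAD4T replicate 3 (adjusted p = 0.0218) and in males of 2 months by DESeq2 (0.0219). The counts are on mouse gene models, so transcripts of a foreign sequence are counted only where they match a mouse gene. Thy1 (ENSMUSG00000032011, chromosome 9, 44043384 to 44048579), a T cell surface gene, was highest in 5 libraries, at 49.9 to 136 CPM. In the same 5 libraries the mean level of 9 thymocyte markers, as log2(CPM + 1), was above 2. These were FAD4T males of 2 months replicates 2 (4.99) and 3 (2.99), FAD4T females of 2 months replicates 1 (3.72) and 2 (4.33), and FAD4T male of 8 months replicate 1 (2.93). The next highest Thy1, 46.2 CPM, was in wild-type male of 2 months replicate 5, whose thymocyte level was 0.38.

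Transcripts of other organs and tissues also differed between libraries. The level of 10 liver genes was 3.54 to 5.18 in the 12 libraries of 8 months and 0.1 to 0.15 in those of 18 months, and the albumin gene Alb lay at 120 to 422 CPM in the 12 libraries of 8 months. Replicate 1 of the wild-type females of 2 months held Alb at 2350 CPM. The level of 10 kidney genes was 0.9 to 1.74 in males of 8 months and wild-type females of 8 months, and 0.05 to 0.07 in FAD4T females of 8 months. Sftpc, a lung surfactant gene, lay at 65.7 to 105 CPM in 5 of the 6 female libraries of 8 months and at 0.899 CPM in the sixth, wild-type replicate 1. The level of 19 skeletal muscle markers went from 1.27 to 9.9 over the 30 libraries.

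**Figure D1:**
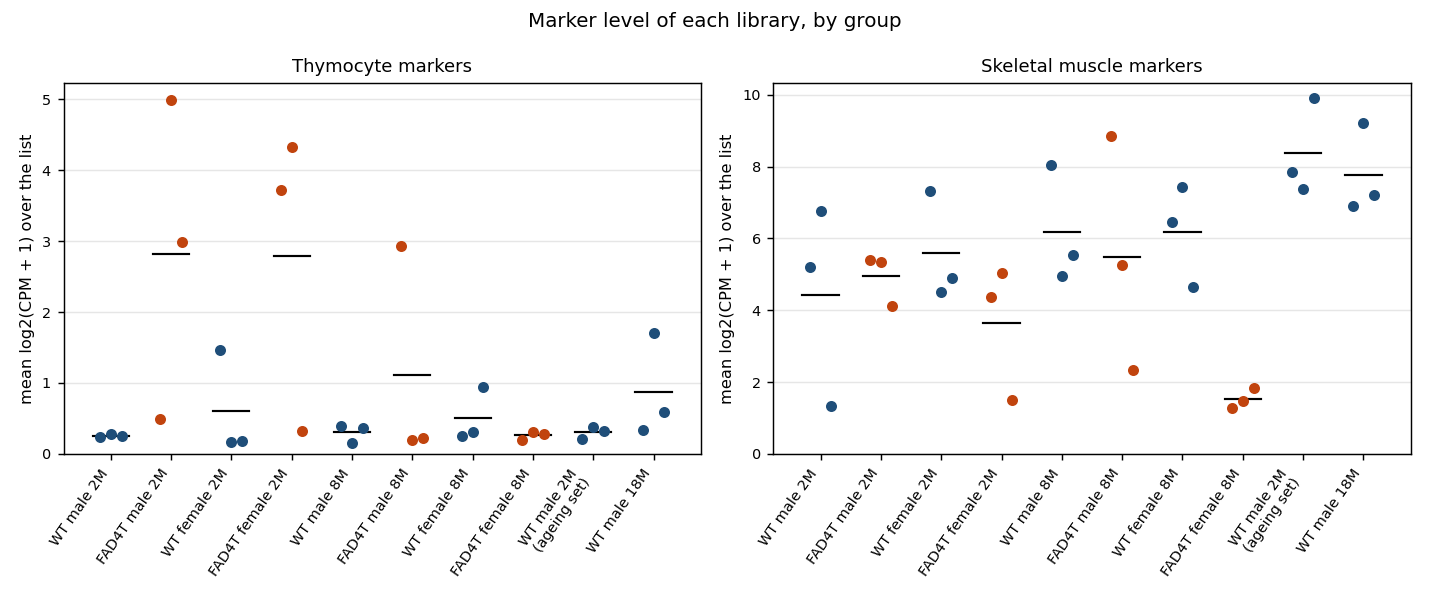
Mean level of the thymocyte markers and of the skeletal muscle markers, as mean log2(CPM + 1) over the list, in each library of the 10 groups (dots, blue for wild type and red for FAD4T; black bars, group means). Thymocyte levels above 2 occur in 5 libraries, all of them FAD4T.

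**Figure D2:**
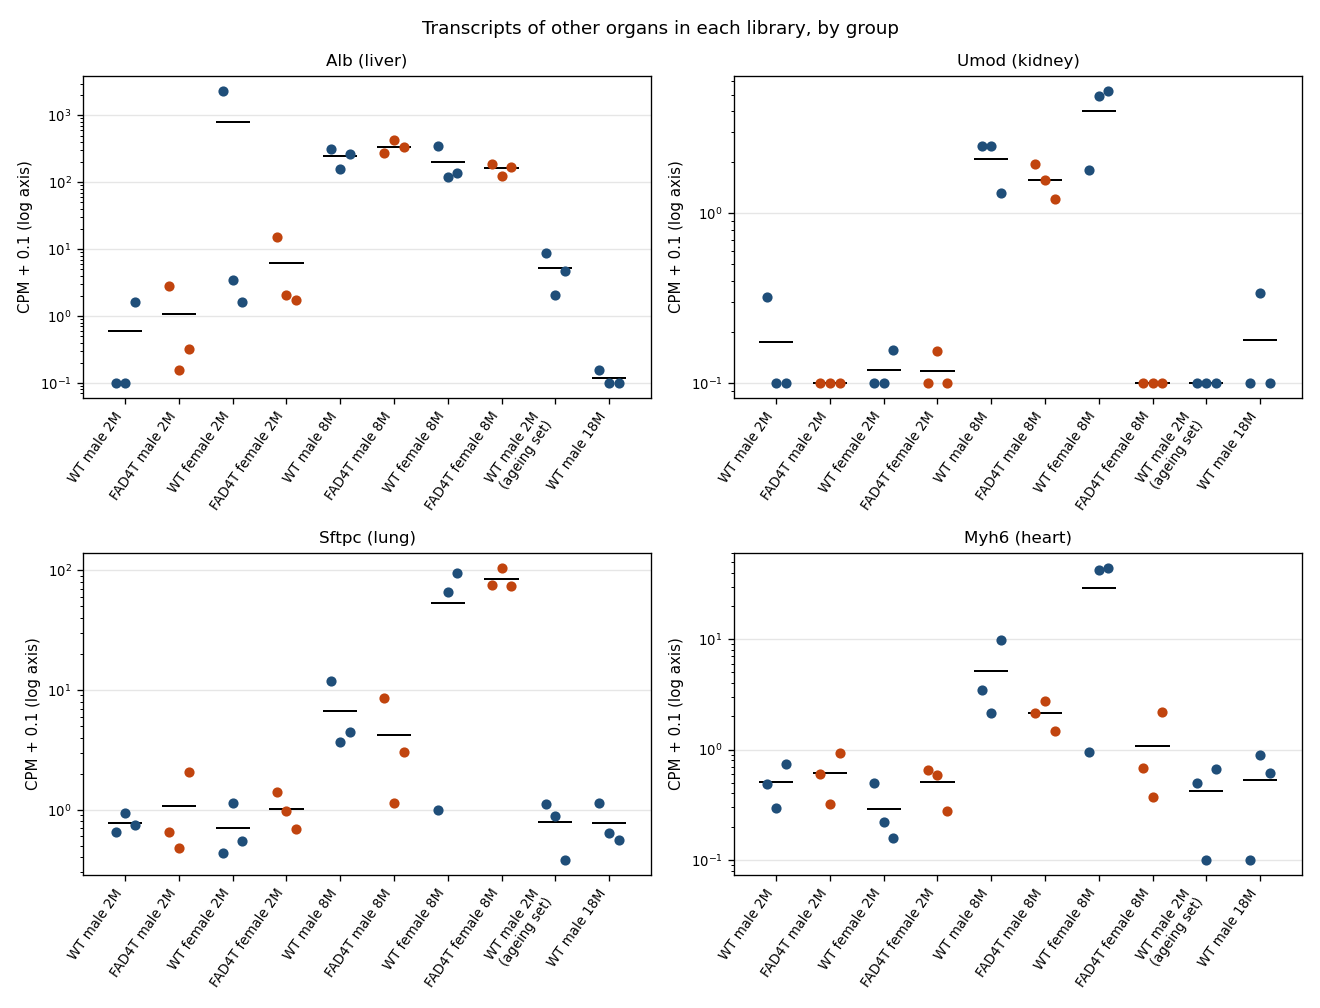
CPM + 0.1 (log axis) of Alb, Umod, Sftpc and Myh6, genes of liver, kidney, lung and heart, in each library of the 10 groups (dots, blue for wild type and red for FAD4T; black bars, group means of CPM + 0.1). Alb lies at 120 to 422 CPM in the 12 libraries of 8 months.

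In males of 2 months, FAD4T thyroids held more transcripts of thymocytes, T cells and the interferon response than wild type. The thymocyte list rose as a group, with a median log2 fold change of 6.31 over 9 measured members (camera adjusted p = 4.18e-05, and adjusted p = 0.583 with an estimated correlation). Cd4 (ENSMUSG00000023274, chromosome 6, 124864692 to 124888221), the co-receptor of helper T cells, was at 14.3 ± 15.9 CPM against 0.356 ± 0.138 (log2 5.28, SE 1.37). The T and NK cell list rose as well, by a median of 3.38 over 9 members (adjusted p = 1.88e-04, and adjusted p = 0.583 with an estimated correlation). Trac, the T cell receptor alpha constant gene, was at 10.8 ± 9.26 against 1.02 ± 0.5 CPM. The FAD4T thymocyte levels were 0.49, 4.99 and 2.99 in replicates 1 to 3, against 0.24 to 0.28 in wild type. FAD4T replicates 2 and 3 also stood apart in the share of Tg (8.86% and 6.68%, against 15.23% in replicate 1 and 12.11% to 21.06% in wild type), in that of mitochondrial transcripts (5.99% and 4.07%, against 2.43% and 1.94% to 3.4%) and in the level of thymic epithelium genes (4.81 and 4.15, against 1.73 and 1.64 to 3.68). Interferon-stimulated genes rose as a group, 18 of 22 being higher, by a median of 0.64 (adjusted p = 4.18e-05, and adjusted p = 0.583 with an estimated correlation). Among them Ifi27l2a (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680) was at 98.3 ± 37.8 against 40.8 ± 7.21 CPM (log2 1.27, SE 0.30). Oas2, an antiviral oligoadenylate synthetase, was at 11.1 ± 3.61 against 3.95 ± 0.536 CPM (log2 1.49, SE 0.43). Adipocyte markers rose by a median of 0.69, 14 of 15 being higher (adjusted p = 5.78e-04, and adjusted p = 0.583 with an estimated correlation). Cfd, the adipokine adipsin, was at 360 ± 161 against 162 ± 21.1 CPM. The adipocyte level was 5.31 to 6.33 in FAD4T and 4.99 to 5.56 in wild type. In the wild-type males of 2 months numbered 4 to 6 it was 6.5 to 6.79. Cell cycle genes rose by a median of 1.73, 19 of 20 being higher (adjusted p = 5.78e-04, and adjusted p = 0.665 with an estimated correlation). The list of amyloid precursor processing and clearance fell by a median of 0.28, 18 of 21 being lower (adjusted p = 0.00666, and adjusted p = 0.583 with an estimated correlation). In that list Aplp2, a homologue of App, was at 360 ± 56 against 508 ± 93.6 CPM, and App itself was at 793 ± 157 against 1010 ± 43.5 CPM (log2 −0.35, SE 0.26).

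No single gene passed in males of 2 months by edgeR over 18493 genes. At an unadjusted p under 0.05 there were 2679 genes where 925 would be expected by chance, and DESeq2 called 102. On simulated counts in this design DESeq2 made 26 false calls of 184 and edgeR 11 of 154. Those counts held no differences shared by many genes between libraries of a group, such as the thymocyte levels here. The simulated rates therefore need not hold for this comparison. Adjusted over the list alone, 9 of 9 thymocyte markers, 7 of 9 T and NK cell markers, 10 of 22 interferon-stimulated genes, 4 of 15 adipocyte markers, 4 of 20 cell cycle genes and 0 of 21 amyloid genes were called. The genes with the smallest p and groups that did not overlap were given by rule as values. With 3 against 3 libraries, chance gives such a gap in 10% of genes. The higher ones were Tap1 (ENSMUSG00000037321, chromosome 17, 34187553 to 34197225), a peptide transporter of antigen presentation, at 40.7 ± 3.93 against 26.4 ± 1.38 CPM (log2 0.62, SE 0.13, adjusted p = 0.343), Pirb at 9.76 ± 2.75 against 4.96 ± 0.928 CPM, and Carmil2 at 21.4 ± 22.5 against 0.969 ± 0.387 CPM. On the lower side were Atf2, a stress-responsive transcription factor, at 43.4 ± 5.16 against 61 ± 5.9 CPM (log2 −0.49, SE 0.13), Klf3 at 88.2 ± 6.06 against 118 ± 6.42 CPM, and Ccser1 with a log2 difference of −0.91. Camera called 14 of the 31 lists, and 7 without FAD4T replicate 1. Without FAD4T replicate 1, 36 genes passed, Ifi27l2a, Trac, Pirb and Carmil2 (each adjusted p = 0.0477) and Ccser1 (0.0482) among them, and without FAD4T replicate 2 the cell cycle list did not pass (0.61). Leaving out the 5 libraries of high thymocyte level was chosen after seeing the data and left 1 FAD4T library here, assumed to vary like the other groups. Then the adipocyte (adjusted p = 0.849) and amyloid (0.247) lists were not called.

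In females of 2 months, FAD4T thyroids held less transcript of cholesterol and fatty acid synthesis and more of antigen presentation. The synthesis list fell by a median of 0.47, 18 of 18 members being lower (camera adjusted p = 2.90e-07, and adjusted p = 0.46 with an estimated correlation). Cyp51 (ENSMUSG00000001467, chromosome 5, 4081145 to 4104746), a sterol demethylase, was at 16.3 ± 2.18 against 28.6 ± 5.01 CPM (log2 −0.81, SE 0.16). Acly, ATP citrate lyase, was at 406 ± 147 against 812 ± 91.3 CPM. The synthesis level was 5.88 to 6.22 in FAD4T and 6.44 to 6.7 in wild type. The same wild-type libraries serve in the comparisons of females of 8 and 2 months and of males and females of 2 months. The lower synthesis levels found there are therefore not independent of this one. The antigen presentation list rose by a median of 0.53, 14 of 15 being higher (adjusted p = 3.78e-06, and adjusted p = 0.46 with an estimated correlation). Among them were the MHC class II genes H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34305877 to 34316199), at 128 ± 10.4 against 79 ± 8.69 CPM, and H2-Aa, at 142 ± 18.2 against 89.6 ± 8.22 CPM. MHC genes share sequence, so the assignment of their reads is uncertain. The thymocyte list rose by a median of 4.18 (adjusted p = 2.81e-04), the T and NK cell list by 2.61 (adjusted p = 3.73e-04) and the cell cycle list by 1.38 (adjusted p = 1.78e-05), each with adjusted p = 0.46 with an estimated correlation. Trac was at 8.44 ± 6.21 against 1.37 ± 0.724 CPM and Mki67, a proliferation marker, at 20.4 ± 16.1 against 2.27 ± 1.61 CPM. The FAD4T thymocyte levels were 3.72, 4.33 and 0.32, against 1.46, 0.17 and 0.18 in wild type. Tg took 8.01%, 4.64% and 19.33% of counts in FAD4T and 5.58%, 18.67% and 19.05% in wild type, and mitochondrial transcripts 6.72%, 6.17% and 2.45% against 5.94%, 2.49% and 2.72%. Thymic epithelium levels were 4.68, 4.64 and 1.52 against 2.44, 1.4 and 1.52. Genes of cytosolic ribosomal proteins fell by a median of 0.35, 17 of 20 being lower (adjusted p = 1.05e-04, and adjusted p = 0.46 with an estimated correlation).

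In females of 2 months edgeR called no gene, with 3087 at an unadjusted p under 0.05 and a smallest adjusted p of 0.153, while DESeq2 called 293 (129 higher, 164 lower). For lists adjusted over the list alone, 4 of 18 synthesis genes, 6 of 15 antigen presentation genes, 5 of 9 thymocyte markers, 3 of 9 T and NK cell markers, 3 of 20 cell cycle genes and 0 of 20 ribosomal protein genes were called. The higher genes given by rule were Cyth4 (ENSMUSG00000018008, chromosome 15, 78597047 to 78622019) at 22.7 ± 6.51 against 10.6 ± 0.673 CPM (log2 1.09, SE 0.20, adjusted p = 0.153), Pheta1 at 85.6 ± 22.4 against 41.3 ± 8.49 CPM, and Dennd3 at 90.6 ± 9 against 56.3 ± 4.19 CPM. Lower were Cyp51, Pemt, which makes phosphatidylcholine, at 3.11 ± 0.444 against 8.03 ± 3.4 CPM, and Rgn with a log2 difference of −2.83. Camera called 15 of the 31 lists. Without FAD4T replicate 3, the library of low thymocyte level, 3001 genes passed, among them the 6 given by rule (Cyth4 at adjusted p = 0.0106) and H2-Eb1 (0.0254), H2-Aa (0.024), Trac (0.0194) and Mki67 (0.0226). The count was 100 without wild-type replicate 2 and 130 without wild-type replicate 3, where Cyth4 had adjusted p = 0.0396 and 0.04. The liver level was 7.28 in wild-type replicate 1, 0.46 and 0.51 in the other wild-type libraries and 0.43 to 1.32 in FAD4T, and without wild-type replicate 1 the log2 difference of Rgn was −0.92. The median of the synthesis list was then −0.53 (adjusted p = 4.68e-05). Without the libraries of high thymocyte level, which leaves 1 FAD4T library here, assumed to vary like the other groups, the ribosomal protein list was not called (adjusted p = 0.0712).

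In males of 8 months, FAD4T thyroids held less transcript of adipocyte genes. That list fell by a median of 0.49, 13 of 15 members being lower (camera adjusted p = 7.88e-10, and adjusted p = 0.508 with an estimated correlation). Cidea (ENSMUSG00000024526, chromosome 18, 67343564 to 67367794), a lipid droplet gene, was at 32 ± 15.4 against 73.4 ± 9.29 CPM (log2 −1.20, SE 0.31). Ucp1, the uncoupling protein of brown fat, was at 45.8 ± 36.4 against 134 ± 48.9 CPM, and Pck1, an enzyme of glyceride and glucose synthesis, at 81.9 ± 51.4 against 183 ± 51.9 CPM. Oxidative phosphorylation genes fell by a median of 0.12, 19 of 20 being lower (adjusted p = 0.00267), and interferon-stimulated genes by 0.17 (adjusted p = 0.00267), both with adjusted p = 0.508 with an estimated correlation. Skeletal muscle markers had a positive median of 0.75 and mean of 0.59, 17 of 19 being higher, while camera ranked the list as lower (adjusted p = 0.00501, and adjusted p = 0.526 with an estimated correlation). Their level was 2.34 to 8.86 in FAD4T and 4.95 to 8.04 in wild type, and the thymocyte level was 2.93 in FAD4T replicate 1 and 0.20 and 0.22 in the other two. The heart level was 1.07 to 1.35 in FAD4T and 1.49 to 2.47 in wild type. The genes given by rule were Bmp2 (ENSMUSG00000027358, chromosome 2, 133552159 to 133562885), a growth factor, at 10.3 ± 0.0976 against 4.89 ± 0.779 CPM (log2 1.08, SE 0.23, adjusted p = 1), Lrrc32 at 23 ± 2.28 against 12.9 ± 0.632 CPM, and Nol4l (log2 0.50). Lower were Ccdc120 at 38.9 ± 2.3 against 62.2 ± 6.82 CPM, Cidea, and Nckap5 (log2 −1.04).

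In males of 8 months edgeR and DESeq2 each called 0 genes, and 335 genes had an unadjusted p under 0.05 by edgeR where 925 would be expected by chance. Cidea was the 1 gene called of the 15 adipocyte markers adjusted over the list alone, and none was called in the interferon, muscle and oxidative phosphorylation lists. Camera called 20 of the 31 lists, and 13, 13 and 12 without FAD4T replicate 1, wild-type replicate 1 and wild-type replicate 2. The interferon list was not called without FAD4T replicate 2 (adjusted p = 0.112) or wild-type replicate 1 (0.137), nor the oxidative phosphorylation list (0.0518 and 0.0864), and the muscle list not without FAD4T replicate 3 (0.173) or wild-type replicate 1 (0.776).

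In females of 8 months, FAD4T thyroids held far less transcript of skeletal muscle genes and less of oxidative phosphorylation and ribosomal proteins. The muscle list fell by a median of 6.80 over 19 members (camera adjusted p = 2.51e-31, and adjusted p = 0.169 with an estimated correlation). Myh1, a fast myosin heavy chain, was at 0.98 ± 0.198 against 176 ± 154 CPM. Atp2a1, the calcium pump of fast muscle, was at 2.84 ± 1.67 against 462 ± 352 CPM, and Tnnt3, fast troponin T, at 2.76 ± 0.181 against 475 ± 412 CPM. The muscle level per library was 1.27 to 1.83 in FAD4T and 4.64 to 7.43 in wild type. Oxidative phosphorylation genes fell by a median of 0.38, 20 of 20 being lower (adjusted p = 1.33e-09, and adjusted p = 0.274 with an estimated correlation). Ndufb9 was at 94.6 ± 2.17 against 131 ± 15.4 CPM. Ribosomal protein genes fell by a median of 0.25, 20 of 20 being lower (adjusted p = 4.68e-06, and adjusted p = 0.608 with an estimated correlation). Endothelial markers rose by a median of 0.24 (adjusted p = 9.64e-04, and adjusted p = 0.608 with an estimated correlation). Vwf, von Willebrand factor, was at 44.6 ± 9.73 against 27.3 ± 7.61 CPM. The thyroid follicular list rose by a median of 0.17, 16 of 21 being higher (adjusted p = 0.0428, and adjusted p = 0.920 with an estimated correlation). Tg was at 262000 ± 43800 against 182000 ± 75200 CPM (log2 0.52, SE 0.55).

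Over all genes in females of 8 months, 4 fell and 0 rose by edgeR, and DESeq2 called 77 (4 higher, 73 lower). A fit of the groups alone called 0, as did one with marker levels as covariates, chosen after seeing the data. These 4 lay outside the naming rule and were chosen after their values were seen. Myh7 (ENSMUSG00000053093, chromosome 14, 54970688 to 54994634), the myosin heavy chain of slow and heart muscle, and Umod (ENSMUSG00000030963, chromosome 7, 119462711 to 119479282), the kidney gene of uromodulin, had adjusted p = 0.0138. Slc34a1 (ENSMUSG00000021490, chromosome 13, 55399648 to 55414695), a phosphate transporter of the kidney tubule, and Tnnc1 (ENSMUSG00000091898, chromosome 14, 31208312 to 31211729), slow and cardiac troponin C, had adjusted p = 0.0381. Umod had 0 counts in FAD4T against 181 in wild type, at least 54.0-fold lower, and Slc34a1 0 against 81, at least 24.2-fold lower, against a floor of 3 counts over the group. Myh7 had 1 count against 118, a ratio of 106 (95% counting interval 18.6 to 4210), and Tnnc1 fell by 3.47 (SE 0.59) on the log2 scale, from 3.78 to 0.333 CPM. Floors and intervals cover counting error only. Kidney, heart and lung levels per library were 0.05 to 0.07, 0.48 to 0.9 and 4.67 to 5.01 in FAD4T, against 0.9 to 1.23, 0.98 to 3.4 and 2.94 to 4.9 in wild type. Within wild type, replicate 1 held heart and lung levels of 0.98 and 2.94. Replicates 2 and 3 each held a heart level of 3.4, with lung levels of 4.25 and 4.9. The genes given by rule as values were Iffo2 at 19.4 ± 1.63 against 11.8 ± 2.04 CPM (adjusted p = 0.516), Col14a1 (log2 0.85), Myh11, the smooth muscle myosin, at 75.6 ± 7.2 against 48.8 ± 13.8 CPM, and the heart muscle genes Myl2 (adjusted p = 0.0534), Mybpc3 (adjusted p = 0.167) and Myl3 (adjusted p = 0.202). Of the muscle markers, 19 of 19 were called adjusted over the list alone, against 1 (Myh7) over all genes. None was called either way in the oxidative phosphorylation, ribosomal protein, endothelial and follicular lists. Camera called 7 of the 31 lists, and 4 without wild-type replicate 3. No gene passed without FAD4T replicate 1, 2 or 3 or wild-type replicate 2, where the adjusted p of Umod was 0.178, 0.0903, 0.131 and 0.0585, of Myh7 0.178, 0.12, 0.131 and 0.0585, of Slc34a1 0.178, 0.132, 0.258 and 0.136, and of Tnnc1 0.491, 0.247, 0.266 and 0.158. Without wild-type replicate 3 it was 0.0646 for Slc34a1 and 0.262 for Tnnc1, and without wild-type replicate 1, 9 genes passed, Myl2 and Mybpc3 (each adjusted p = 0.00346) among them. The endothelial list was not called without FAD4T replicate 3 (adjusted p = 0.0529) or wild-type replicate 2 (0.128), nor the follicular list without FAD4T replicate 1 (0.803), wild-type replicate 2 (0.606) or wild-type replicate 3 (0.116).

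No gene was called in more than 1 of the 4 FAD4T comparisons by edgeR, and 18 were by DESeq2. As edgeR called 0 genes in both sexes at 2 months and in males of 8 months, no overlap was possible. Its absence therefore says nothing of shared effects. The comparisons share no library. Across 18493 genes, which are not independent replicates, log2 fold changes of males and females of 2 months correlated with Pearson's r = 0.37 and Spearman's rho = 0.53, and those of 8 months with −0.06 and 0.10. At an unadjusted p under 0.05, 572 genes were higher in both sexes at 2 months where 147.3 were expected of independent lists, and 176 lower where 80 were expected. Both FAD4T groups of 2 months held libraries of high thymocyte level (male replicates 2 and 3, female replicates 1 and 2). Whether the shared genes come from these libraries was not tested, so the overlap does not show an effect of the genotype shared by the sexes. At 8 months 15 were higher where 2.9 were expected and 17 lower where 4.5 were. The difference of the FAD4T effect between sexes or ages passed for 0 genes in each of 4 edgeR tests. At an unadjusted p under 0.05 there were 744 genes between the sexes at 2 months, 369 at 8 months, 922 between the ages in males and 1520 in females, and DESeq2 called 33, 9, 16 and 16. Without replicate 1 of the FAD4T females of 2 months, 1 gene passed between the ages in females. Camera called 38 lists over them, 0 with an estimated correlation. The largest was the skeletal muscle list, whose male minus female FAD4T effect at 8 months had a median of 7.48. Tg did not pass in any FAD4T comparison, nor did 4 other thyroid genes fixed with it, with adjusted p from 0.243 to 1.

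Between 18 and 2 months in wild-type males, genes of the unfolded protein response rose and genes of adipocytes, oxidative phosphorylation, ribosomal proteins and endothelium fell. Hspa5 (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), the main chaperone of the endoplasmic reticulum, rose to 3670 ± 926 from 634 ± 94.5 CPM (log2 2.53, SE 0.24, edgeR adjusted p = 8.18e-04). Pdia4, a disulfide isomerase there, rose to 921 ± 240 from 207 ± 31.7 CPM (log2 2.15, SE 0.22, adjusted p = 9.69e-04). Edem1, of endoplasmic reticulum degradation, rose to 151 ± 29.5 from 44.3 ± 1.16 CPM. In that list 11 of 19 members rose and the median was 1.02 (camera adjusted p = 1.79e-05, and adjusted p = 0.903 with an estimated correlation). Adipocyte markers had a median of −2.15 with 11 of 15 falling (adjusted p = 2.23e-06). Adipoq, the gene of adiponectin, fell to 21.3 ± 7.77 from 119 ± 4.82 CPM (log2 −2.48, SE 0.27, adjusted p = 0.00134). Oxidative phosphorylation genes had a median of −1.06 with 18 of 20 falling (adjusted p = 4.81e-07). Cox4i1, a subunit of cytochrome c oxidase, fell to 258 ± 17.2 from 600 ± 99.5 CPM. All 20 ribosomal protein genes fell (median −1.09, adjusted p = 5.44e-09). Of 12 endothelial markers 7 fell (median −0.56, adjusted p = 0.0107), such as Egfl7 to 40.9 ± 1.97 from 99.9 ± 5.1 CPM. These 4 lists also had adjusted p = 0.903 with an estimated correlation, and fry called all 5. Camera called no other list here, and 11 lists without 2-month replicate 6 and 9 without 18-month replicate 2. With 2-month libraries 1 to 3 as the young group, in a fit of all 30 libraries, the oxidative phosphorylation list was not called (median −0.09, adjusted p = 0.602, 0 of 20 members called). The ribosomal protein median was then −0.41 with 3 of 20 called and the adipocyte median −0.84 with 5 of 15. Relative to genes of matched length, the oxidative phosphorylation median was −0.35 and the ribosomal protein median −0.25. The muscle level was 6.90 to 9.21 at 18 months and 7.38 to 9.90 at 2 months, and the thymocyte level was 1.70 in replicate 2 of 18 months.

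In the circadian clock list 4 of 15 members rose and 10 fell between 18 and 2 months (fry adjusted p = 0.0235, camera adjusted p = 0.0903, and adjusted p = 0.903 with an estimated correlation). Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), the clock activator BMAL1, rose to 33 ± 5.13 from 3.02 ± 0.96 CPM (log2 3.44, SE 0.26, adjusted p = 7.06e-04). Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), a target of it, fell to 21.6 ± 10.8 from 230 ± 39.2 CPM (log2 −3.41, SE 0.41, adjusted p = 0.00248). Clock (log2 1.12), Npas2 (log2 1.66), Tef (log2 −1.73) and Per3 (log2 −1.87) also passed and Per2 (log2 −0.05) did not, these 5 being named after their values were seen. With 2-month libraries 1 to 3 as the young group Clock did not pass (log2 0.31, adjusted p = 0.407). The hour of dissection is not given in the sources used here. Tshr (ENSMUSG00000020963, chromosome 12, 91400994 to 91540509), the receptor of thyrotropin, rose to 111 ± 18.7 from 37 ± 6.5 CPM (log2 1.59, SE 0.17, adjusted p = 9.81e-04). Tg, Slc5a5, Pax8 and Dio1, genes of hormone synthesis, iodide uptake, thyroid identity and hormone activation, did not pass, with adjusted p from 0.26 to 0.845, except Slc5a5 without 2-month replicate 6 (0.00437).

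**Figure D3:**
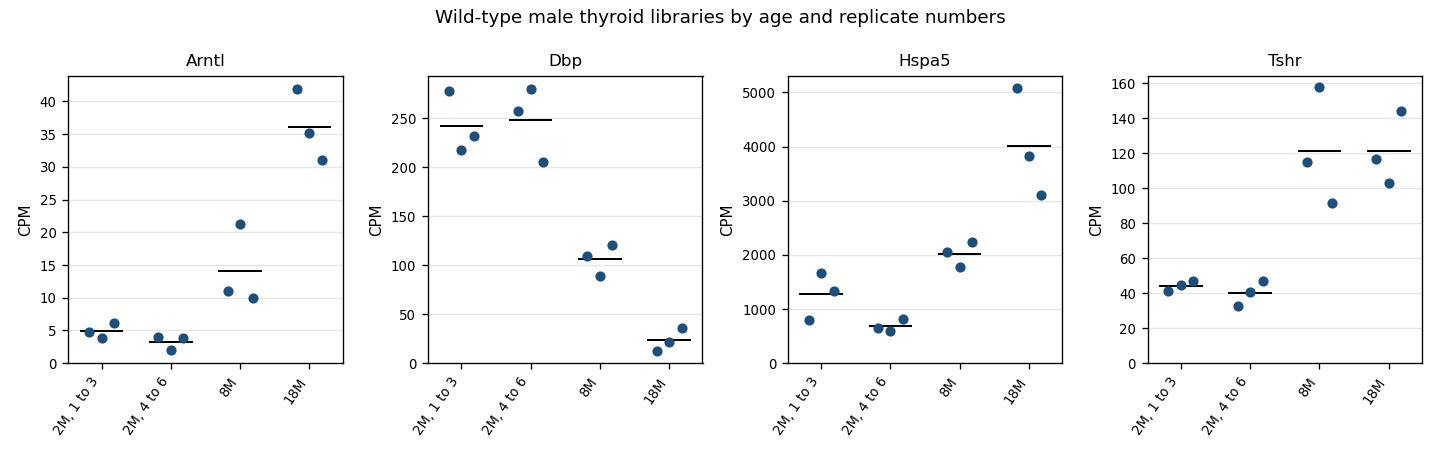
CPM of Arntl, Dbp, Hspa5 and Tshr (linear axes from 0) in each wild-type male library of 2 months (replicates 1 to 3), 2 months (replicates 4 to 6), 8 months and 18 months (dots; black bars, group means). Arntl, Hspa5 and Tshr rose and Dbp fell at 18 months against replicates 4 to 6 by edgeR.

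Of 16283 genes tested between 18 and 2 months, 5840 (35.9%) passed, 2782 rising and 3058 falling. At an unadjusted p under 0.05 there were 7552 where 814 would be expected. The largest rises by rule were Csmd2 (ENSMUSG00000028804, chromosome 4, 127987857 to 128567656) to 9.5 ± 1.69 from 0.407 ± 0.107 CPM (log2 4.51, SE 0.32), Nexmif (log2 3.80, SE 0.47), Bdkrb2, a bradykinin receptor (log2 3.58), Cd209f (log2 3.50) and Arntl. They were followed by Lancl3 (log2 3.37), Vcl, the gene of the adhesion protein vinculin (ENSMUSG00000021823, chromosome 14, 20929433 to 21033673), to 53.3 ± 0.816 from 5.17 ± 2.03 CPM (log2 3.36, SE 0.26), Foxf2 (log2 3.33), Cyp27b1, which activates vitamin D, to 32.3 ± 11.3 from 3.27 ± 0.9 CPM (log2 3.31, SE 0.34), and Selp, P-selectin (log2 3.20). The largest falls were Cyp2e1 (ENSMUSG00000025479, chromosome 7, 140763739 to 140774987), a cytochrome P450, to 10.5 ± 3.04 from 250 ± 72.3 CPM (log2 −4.57, SE 0.31), and Pck1 to 14.2 ± 6.67 from 239 ± 73.6 CPM (log2 −4.08, SE 0.45). Then came Cidea (log2 −3.55), Dbp, Pla2g4f (log2 −3.33), Prkag2os1 (log2 −2.81), a gene antisense to another whose reads cannot be told apart without strand, Col9a1 (log2 −2.73), and Adig, Hif3a and Cidec (each log2 −2.65). For each list adjusted over the list alone, 12 of 19 unfolded protein response genes rose and 13 of 15 adipocyte, 19 of 20 oxidative phosphorylation, 20 of 20 ribosomal protein and 7 of 12 endothelial genes fell. Without replicate 5 of the 2-month set 3651 genes passed, and the endothelial list was not called without replicate 4 (adjusted p = 0.054). Cidea did not pass without 2-month replicate 6 (0.0501) or 18-month replicate 2 (0.0666). With 2-month libraries 1 to 3 as the young group, 1776 genes passed (842 rising, 934 falling), and Vcl (log2 1.52, adjusted p = 0.072), Lancl3 (log2 1.04, 0.351), Hif3a (0.463), Adig (0.124), Cidec (0.0649), Prkag2os1 (0.39) and Cox4i1 (0.279) did not. That fit held all 30 libraries and the main one 6, so the young group is not all that differs between the counts. Differences were also smaller for Adipoq (log2 −1.09), Cyp2e1 (log2 −2.35), Pck1 (log2 −2.08), Cidea (log2 −1.62), Hspa5 (log2 1.64) and Edem1 (log2 1.15), which passed. With all 6 libraries of 2 months as the young group Cidea did not pass (adjusted p = 0.0664).

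Between 8 and 2 months in wild-type males, transcripts of the mitochondrial genome, adipocytes and airway epithelium rose and those of endothelium, extracellular matrix and the circadian clock fell. mt-Atp6 (ENSMUSG00000064357, mitochondrial genome, 7927 to 8607) rose to 32.5 ± 7.19 from 7.21 ± 1.98 CPM (log2 2.17, SE 0.32, edgeR adjusted p = 0.00311) and mt-Atp8 to 2.52 ± 1.3 from 0.323 ± 0.0221 CPM (log2 2.93, SE 0.48, adjusted p = 0.00503). Both encode ATP synthase subunits and overlap, so their reads are shared in part. That list had a median of 0.56 with 4 of 13 rising (camera adjusted p = 3.48e-08). Endothelial markers fell by a median of 0.56 (adjusted p = 1.67e-06), and extracellular matrix genes by 0.37 (adjusted p = 3.47e-06), with the collagen gene Col3a1 at 90.9 ± 20 against 188 ± 11 CPM (adjusted p = 0.0629). Circadian clock genes fell by 0.50 (adjusted p = 0.00568), with Dbp at 108 ± 17 against 247 ± 31 CPM (adjusted p = 0.0907). Adipocyte markers rose by a median of 0.73 (adjusted p = 4.38e-06), oxidative phosphorylation genes by 0.32, 20 of 20 being higher (adjusted p = 1.95e-05), and airway markers by 1.63, 12 of 12 being higher (adjusted p = 2.31e-05). Each of these 7 lists had adjusted p = 0.33 with an estimated correlation. The adipocyte level was 5.96 to 6.05 at 8 months and 4.99 to 5.56 in the 2-month libraries 1 to 3 used here. In the 2-month libraries 4 to 6 it was 6.5 to 6.79, above the 8-month level. The oxidative phosphorylation level was likewise 7.42 to 7.6 at 8 months, 7.09 to 7.23 in libraries 1 to 3 and 7.89 to 8.49 in libraries 4 to 6. Fat4 (ENSMUSG00000046743, chromosome 3, 38886940 to 39011985), an atypical cadherin, fell to 4.93 ± 0.22 from 12.4 ± 3.1 CPM (log2 −1.33, SE 0.20, adjusted p = 0.00311). H2-M9 (ENSMUSG00000067201, chromosome 17, 36639285 to 36642666), an MHC class I gene whose reads are uncertain among close paralogs, fell to 3.51 ± 0.895 from 10.7 ± 0.779 CPM (log2 −1.61, SE 0.25, adjusted p = 0.00311).

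Kap (ENSMUSG00000032758, chromosome 6, 133849851 to 133853762), an androgen-regulated kidney gene, rose in males of 8 months with 1170 counts against 1, a ratio of 1110 (95% counting interval 199 to 43900, adjusted p = 0.00558). The liver and kidney levels of these libraries stood at 3.98 to 4.94 and 1.17 to 1.74, against 0.11 to 0.4 and 0.04 to 0.1 at 2 months, and the lung and heart levels at 2.92 to 3.6 and 1.49 to 2.47, against 2.51 to 2.62 and 0.45 to 0.67. By edgeR 128 genes passed in this comparison, 78 rising and 50 falling, while library totals as the only scaling, chosen after seeing the data, gave 133, 61 rising and 72 falling. DESeq2 called 489, a fit of the groups alone 455 (347 rising, 108 falling) and a fit with no filter on low counts 78. When adjusted over the list alone, 5 of 13 mitochondrial, 7 of 12 endothelial, 5 of 19 matrix and 6 of 15 adipocyte genes were called, against 4, 1, 0 and 0 over all genes. Of 15 clock genes 1 was higher and 4 lower adjusted over the list alone, against 1 and 0 over all genes, and no oxidative phosphorylation or airway gene was called either way. Camera called 15 lists. The count was 30, 44 and 36 without 2-month replicates 1, 2 and 3, and 31, 55 and 39 without 8-month replicates 1, 2 and 3, and Kap did not pass without 2-month replicate 1 (adjusted p = 0.061) or 3 (0.0566).

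Between 8 and 2 months in wild-type females, interferon-stimulated and cholesterol synthesis genes fell while airway, immediate early and antigen presentation genes rose. The interferon list fell by a median of 0.82 (camera adjusted p = 1.17e-12, and adjusted p = 0.25 with an estimated correlation). Bst2 (ENSMUSG00000046718, chromosome 8, 71534255 to 71537456), the antiviral protein tetherin, fell to 32.9 ± 2.38 from 57.3 ± 9.43 CPM (log2 −0.80, SE 0.15, edgeR adjusted p = 0.0246). Airway markers rose by a median of 2.52 (adjusted p = 2.85e-08, and adjusted p = 0.25 with an estimated correlation). Scgb1a1, the club cell secretoglobin, was at 263 ± 229 against 0.874 ± 0.459 CPM (adjusted p = 0.0541). Sftpa1 (ENSMUSG00000021789, chromosome 14, 41131782 to 41136452), a lung surfactant gene, rose to 10.3 ± 8.91 from 0.294 ± 0.251 CPM (log2 5.10, SE 0.73, adjusted p = 0.00538). Mybpc3, a heart muscle gene, rose with 257 counts against 1, a ratio of 280 (95% counting interval 49.8 to 11100, adjusted p = 0.00847). The lung level was 2.94 to 4.9 at 8 months and 2.34 to 2.72 at 2 months, and the heart level 0.98 to 3.4 and 0.33 to 0.82. Replicate 1 of 8 months stood apart with the lowest lung and heart levels of its group, the other lung levels being 4.25 and 4.9. The kidney level was 0.9 to 1.23 at 8 months and 0.05 to 0.15 at 2 months. The liver level was 3.54 to 5.18 at 8 months and 0.46 to 7.28 at 2 months. Immediate early and heat shock genes rose by a median of 0.48, 16 of 16 being higher (adjusted p = 4.96e-06, and adjusted p = 0.276 with an estimated correlation). The antigen presentation list rose by 0.23 (adjusted p = 3.97e-05, and adjusted p = 0.475 with an estimated correlation), and transcripts of the mitochondrial genome by 0.05, with a mean of 0.68 (adjusted p = 6.36e-05, and adjusted p = 0.622 with an estimated correlation). Cholesterol and fatty acid synthesis fell by 0.27 (adjusted p = 1.61e-05, and adjusted p = 0.373 with an estimated correlation), with Acly at 321 ± 108 against 812 ± 91.3 CPM (adjusted p = 0.109). The interferon level was 3.13 to 3.64 at 8 months and 3.58 to 4.31 at 2 months. The synthesis level was 5.93 to 6.46 and 6.44 to 6.7. These 2-month females also serve in the FAD4T comparison and in that with males, so results shared with those are not independent. Il17rb (ENSMUSG00000015966, chromosome 14, 29996141 to 30008896), an interleukin receptor, fell to 44.3 ± 7.15 from 101 ± 13.7 CPM (log2 −1.19, SE 0.22, adjusted p = 0.0206).

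In these females 47 genes passed by edgeR, 38 rising and 9 falling, while DESeq2 called 267, a fit of the groups alone 1 and one with 1 surrogate variable 71. Choices made after seeing the data gave 148 with marker levels as covariates and 29 with library totals. In the lists adjusted over the list alone, 15 of 22 interferon genes fell and 4 of 12 airway, 5 of 15 antigen presentation and 5 of 13 mitochondrial genes rose, against 1, 0, 0 and 2 over all genes. Of 18 synthesis genes 4 were lower adjusted over the list alone and 0 over all genes, and no immediate early gene was called either way. Camera called 9 lists. The count was 211 and 14 without 2-month replicates 1 and 3, and 78, 10 and 31 without 8-month replicates 1, 2 and 3. Bst2 and Il17rb did not pass without 2-month replicate 3 (adjusted p = 0.091 and 0.125), 8-month replicate 2 (0.149 and 0.116) or 8-month replicate 3 (0.102 and 0.132), nor Mybpc3 without 2-month replicate 3 (0.0806), and Scgb1a1 passed without 8-month replicate 1 (0.0186).

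Between wild-type males numbered 1 to 3 and wild-type females of 2 months, interferon-stimulated, adipocyte and lipid synthesis genes were lower in males. The interferon list was lower by a median log2 difference of −0.93 (camera adjusted p = 5.85e-22, and adjusted p = 0.0406 with an estimated correlation, so that this call held). Bst2 was lower in males at 30 ± 7.48 against 57.3 ± 9.43 CPM (log2 −0.93, SE 0.15, edgeR adjusted p = 0.0136). Adipocyte markers had a median of −0.94 (adjusted p = 2.00e-16, and adjusted p = 0.0659 with an estimated correlation). Retn (ENSMUSG00000012705, chromosome 8, 3655770 to 3660110), the fat hormone resistin, was lower in males at 22.1 ± 4.13 against 64.8 ± 10.7 CPM (log2 −1.56, SE 0.26, adjusted p = 0.0136). The synthesis list had a median of −0.50 (adjusted p = 1.14e-11, and adjusted p = 0.0659 with an estimated correlation), with Cyp51 at a log2 difference of −0.81 (SE 0.16, adjusted p = 0.082). Immediate early and heat shock genes were higher in males by a median of 0.58 (adjusted p = 3.94e-07, and adjusted p = 0.138 with an estimated correlation). The liver level of the females was 0.46 to 7.28 and of the males 0.11 to 0.4. The adipocyte level was 4.99 to 5.56 in these males and 5.95 to 6.65 in the females. It was 6.5 to 6.79 in the 2-month males numbered 4 to 6, so that difference depends on the males used. Interferon and synthesis levels of numbers 4 to 6 were 3.29 to 3.59 and 5.89 to 6.17, against 3.58 to 4.31 and 6.44 to 6.7 in the females. The same females serve in the FAD4T and 8-month comparisons, so results shared with those are not independent. Of 14 genes that passed, 8 were autosomal, 2 higher and 6 lower in males, 1 X-linked and 5 Y-linked. DESeq2 called 271, a fit of the groups alone 4, one without X and Y genes 3 and one with marker levels as covariates, chosen after seeing the data, 23. With each list adjusted over the list alone, 16 of 22 interferon, 12 of 15 adipocyte and 6 of 18 synthesis genes were lower in males, against 2, 2 and 0 over all genes, and 2 of 16 immediate early and heat shock genes were higher, against 0. Camera called 9 lists. The count was 7, 26 and 7 without male replicates 1, 2 and 3, and 6, 252 and 228 without female replicates 1, 2 and 3. Bst2 did not pass without male replicate 1 (adjusted p = 0.0757) or female replicate 1 (0.106), nor Retn without male replicate 1 (0.0822), male replicate 3 (0.149) or female replicate 1 (0.0957). Cyp51 passed without male replicate 2 (0.0145) or female replicate 2 (0.0348) or 3 (0.0144).

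Between wild-type males and females of 8 months, extracellular matrix genes were lower in males, 19 of 19 members having a negative difference with a median of −0.45 (camera adjusted p = 6.20e-14, and adjusted p = 0.0363 with an estimated correlation, so that this call held). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), a collagen I chain, was at 30.1 ± 4.97 against 151 ± 90.2 CPM (log2 −2.33, SE 0.38, edgeR adjusted p = 0.00599). Col1a2 was at 54 ± 10.6 against 143 ± 54.9 CPM (log2 −1.41, SE 0.24, adjusted p = 0.00831). Mmd2 (ENSMUSG00000039533, chromosome 5, 142562358 to 142608800) was lower in males at 0.133 ± 0.0237 against 11.7 ± 4.81 CPM (log2 −6.37, SE 0.80, adjusted p = 2.80e-04). C7 (ENSMUSG00000079105, chromosome 15, 4988762 to 5063773), a complement component, was higher at 12.6 ± 4.49 against 1.77 ± 0.464 CPM (log2 2.83, SE 0.40, adjusted p = 0.00109). Dnase1l2 was also higher, at 46 ± 6.46 against 15.4 ± 2.81 CPM (adjusted p = 0.00128). The lung level was 2.92 to 3.6 in males and 2.94, 4.25 and 4.9 in female replicates 1 to 3, so female replicate 1 lay among the males. Obp2a also set that replicate with the males, at 18.5 CPM against 6.76 to 43.9 CPM in males. Female replicates 2 and 3 held Obp2a at 0.067 and 0 CPM. The source of this likeness was not tested, so calls between these groups may not come from sex alone. Of 50 genes that passed, 42 were autosomal, 12 higher and 30 lower in males, 3 X-linked and 5 Y-linked. DESeq2 called 96. Of the matrix genes 8 of 19 were lower in males adjusted over the list alone, against 4 over all genes. Camera called 3 lists, and 1 without male replicate 3. The count was 25, 23 and 28 without male replicates 1, 2 and 3, and 84, 30 and 26 without female replicates 1, 2 and 3. Col1a1 (adjusted p = 0.0672) and Col1a2 (0.0937) did not pass without male replicate 2, nor Col1a2 without female replicate 2 (0.0748).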

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

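The difference of the FAD4T effect between sexes or between ages was tested for every gene list, and 38 tests passed by camera, 15 of them with a median log2 difference of at least 1 in size. None of the 15 passed with an estimated correlation, where adjusted p went from 0.391 to 0.851. For the patterns weighed in this part, the tests of the follicular share, of the genotype and of the organ genes were chosen after the result was seen. The thymic epithelium test was set before its own result was seen. Its genes were listed after the first results, and it was built on the libraries of high thymocyte level, so that pattern was already known. Each median is the male minus the female effect, or the 8-month minus the 2-month effect, and n = 3 libraries per group.

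Between the sexes at 2 months, the skeletal muscle list differed by 1.49 (camera adjusted p = 6.61e-05) and the airway list by 2.70 (adjusted p = 1.29e-04). At 8 months the muscle list differed by 7.48 (adjusted p = 1.02e-19), the airway list by 1.19 (adjusted p = 0.00831) and the thymocyte list by 4.53 (adjusted p = 0.0235), or by 4.75 with genes at 0 counts in a group set to their floor. Between the ages in males, the muscle list had a median of 1.38 while camera ranked it as lower (adjusted p = 0.0319). The adipocyte list differed by −1.05 (adjusted p = 1.76e-09), the thymocyte list by −2.18 (adjusted p = 0.0168) and the T and NK cell list by −1.91 (adjusted p = 0.0263). Between the ages in females, the muscle list differed by −4.65 (adjusted p = 1.11e-05), stratified epithelium by −3.35 (adjusted p = 0.039), thymocytes by −5.56 (adjusted p = 8.32e-04), T and NK cells by −2.79 (adjusted p = 0.00355), B and plasma cells by −1.19 (adjusted p = 0.00919) and the cell cycle by −1.15 (adjusted p = 9.12e-04). No test of whether a library stands apart from its group was run. The 4 counts of single genes were 0, which each of the 25 splits of the labels behind them reaches whatever the data, so these splits say nothing of chance. The highest count among the other splits was 9219 for the sexes at 2 months, which points to a structure of the samples, and 1, 0 and 0 for the other three.

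Thymocyte and lymphocyte transcripts were high in 4 of the 6 FAD4T libraries of 2 months. A lower share of follicular cells as the only cause would raise the markers of all other cells alike. The medians of 5 cell type lists in females of 2 months lay 6.47 log2 units apart, which argues against it as the only cause. The 5 include the thymocyte list that prompted the test and the muscle list, which varies widely between libraries. So the spread cannot exclude a lower share beside another source. Tg took 8.86% and 6.68% of counts in the male libraries of high thymocyte level and 8.01% and 4.64% in the female ones, all of 2 months. Thymus tissue in the dissected sample stays a candidate source. The mean level of 5 thymic epithelium genes was 3.79 to 4.81 in the 5 libraries of high thymocyte level. In 5 of these 5 it was above the highest of the 25 others (3.68). Prss16 was at 54.2 ± 47.4 CPM in FAD4T and 11.7 ± 17.7 CPM in wild-type males of 2 months. In those wild-type males all 5 genes had a mean of at least 1 CPM. For Psmb11 that mean rested on replicate 1 (4.08 CPM, against 0.322 and 0.0584 CPM). Psmb11 was at 3.3 to 8.78 CPM in the 5 libraries of high thymocyte level. Foxn1 of that list did not follow, at 3.16 to 6.75 CPM in the 5 libraries and 1.74 to 6.59 CPM in the others, and the level of 3.68 was that of wild-type male of 2 months replicate 1, with a thymocyte level of 0.24 and Prss16 at 32.1 CPM. The FAD4T minus wild-type difference in thymocyte level at 2 months was 2.38 (exact 2-sided permutation p of 0.025 over 400 permutations within each sex), which restates what prompted the test and supports no explanation. The genotype and a difference in dissection between the genotypes stay open, and nothing in the labels separates them.

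Liver, kidney, heart and lung transcripts were present in libraries of 8 months. Age as the cause of the liver transcripts would need them at 18 months too, and in 3 of 3 libraries of 18 months the liver level (0.1 to 0.15) was below the lowest of the 12 libraries of 8 months (3.54), which argues against age alone. The same holds for kidney in males, with 3 of 3 libraries of 18 months (0.07 to 0.12) below the lowest of the 6 males of 8 months (1.13). For heart and lung the age of the animals stays open, since 0 of these 2 organs lay below the 6 males of 8 months in every library of 18 months (1.04 to 1.56 and 2.51 to 2.91, against 1.07 to 2.47 and 2.81 to 3.6). RNA or reads of other organs stay open as a candidate source. That 10 of 10 liver genes had a higher mean over the 12 libraries than in wild-type males of 2 months restates the pattern and supports no explanation. Alb was at 343 ± 75.6 CPM in FAD4T and 246 ± 82 CPM in wild-type males of 8 months against 0.506 ± 0.877 CPM. At 1 CPM or more in those 2-month males were 0 of 10 liver, 0 of 10 kidney, 2 of 9 heart and 3 of 8 lung genes. Whether such RNA entered at dissection, library preparation or sequencing cannot be seen in counts. The kidney, heart and lung genes differed between groups of the same age, so part of the calls in 8-month comparisons, Umod, Slc34a1 and Kap among them, may come from this source.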

How the results depend on the processing

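Of 252 alternatives to the 15 main counts, 188 stayed within 1.5 times the reported count and 64 moved further. Several main counts were 0, and a 0 that stayed 0 counts among the 188. So the tally does not measure how stable the called genes are. For 8 against 2 months in males, 128 genes became 30 to 55 with each library left out. For 44 gene lists described in the report, 578 of 685 alternatives kept direction and call, 101 lost the call and 6 turned direction, and for 119 named genes 1557 of 1727 kept both, 75 lost a call, 67 gained one and 28 turned sign. The tests with marker levels as covariates, with library totals as the only scaling and without the libraries of high thymocyte level were chosen after seeing the data. Unless said otherwise the cause of a change was not tested. DESeq2 called 102 and 293 genes for FAD4T at 2 months (males, females), 77 in females of 8 months, 489 and 267 for 8 against 2 months (males, females), 271 and 96 for male against female (2 months, 8 months), 33 and 9 for genotype by sex, 16 and 16 for genotype by age, and 18 genes in more than 1 FAD4T comparison. It stayed within 1.5 times in males of 8 months (0) and for 18 against 2 months (6259). Of 135 list calls by camera, 2 held with an estimated correlation and 9 with fry, which called 12 lists in all. The number of lists called per comparison also moved by over 1.5 times for 18 against 2 months (from 5 to 9 with all 6 young libraries or library totals, 11 with no filter and 12 with libraries 1 to 3), and with 1 surrogate variable for 8 against 2 months in males (15 to 9) and male against female at 8 months (3 to 1). With marker levels as covariates it was 8 and 11 in FAD4T females of 2 and males of 8 months, 9 for 8 against 2 months in males and 1 for male against female at 8 months. For the interactions it lay between 4 and 18 where it moved so far.

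With no filter on low counts, 78 genes were called for 8 against 2 months in males, 2 for genotype by sex at 8 months and 2 for genotype by age in females. A fit of only the groups compared, with 4 residual degrees of freedom, gave 0 for FAD4T females of 8 months, 455 and 1 for 8 against 2 months (males, females) and 4 for male against female at 2 months. With 1 surrogate variable 71 genes were called for 8 against 2 months in females, and with X and Y genes left out 3 for male against female at 2 months. With the title number as a block, the count in FAD4T females of 8 months was 1, and in the males of 8 months, taken as paired, the block changed no call of a gene or of a list described. In the other comparisons the libraries share only a number: correlations of same-numbered libraries were −0.39, −0.04 and −0.02 in FAD4T males of 2 months, 0.16, −0.41 and 0.46 in females of 2 months and 0.46, 0.22 and 0.04 in females of 8 months, where 0, 3 and 3 of 6 libraries correlated best with their own number. For 8 against 2 months 3 and 2 of 6 did so (males, females), and for male against female 2 and 3 (2 months, 8 months), with 94, 41, 14 and 48 genes called under the block. No paired analysis was possible because the numbers of the 2-month and 18-month males of the ageing comparison are not shared.

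For 18 against 2 months, 1776 genes were called with libraries 1 to 3 as the young group, in a fit of all 30 libraries. With all 6 as the young group, in a fit of 9 libraries, 1417 were called (733 rising, 684 falling). The main fit held 6 libraries, so these counts also differ in the fit. With libraries 1 to 3 the difference of Slc5a5 (−0.36), not called, turned negative. Marker levels as covariates gave 0 for FAD4T females of 8 months, 148 for 8 against 2 months in females and 23 for male against female at 2 months. With them the thymocyte (adjusted p = 0.939), T and NK cell (0.953) and cell cycle (0.21) lists turned direction in FAD4T males of 2 months, as did App in females of 2 months (0.03), Tg in males of 8 months (0.23) and Thy1 in females of 8 months (0.06), which were not called. Library totals as the only scaling gave 29 for 8 against 2 months in females, turned Prnp in males of 2 months (0.05) and females of 8 months (−0.06) and Per2 at 18 months (0.04), and moved the median of all genes by 0.16 for FAD4T at 2 months in both sexes, so changes there are relative to that. Without the libraries of high thymocyte level 1 FAD4T library of 2 months is left in each sex, assumed to vary like the other groups, and since they were left out for that level, the thymocyte and T cell values say nothing of stability. No gene then passed for FAD4T at 2 months, with 353 and 633 genes at an unadjusted p under 0.05 (males, females). In FAD4T females of 2 months the thymocyte (adjusted p = 0.261) and T and NK cell (0.631) lists then turned direction, as did App (0.29) and Tg (0.42), in males of 2 months Prnp (0.03), and in males of 8 months Thy1 (−0.03) and Prnp (−0.02).

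Leaving out each library in turn gave 0 to 36 genes for FAD4T males and 0 to 3001 for FAD4T females of 2 months, 0 to 0 and 0 to 9 for those of 8 months, 3651 to 5470 for 18 against 2 months, 30 to 55 and 10 to 211 for 8 against 2 months (males, females), and 6 to 252 and 23 to 84 for male against female (2 months, 8 months). The interactions gave 0 to 0, except genotype by age in females with 0 to 1. The muscle list of FAD4T males of 8 months turned direction without FAD4T replicate 3 (adjusted p = 0.173, against 6.59e-16 to 0.776 over all libraries left out). Log2 differences of uncalled genes near 0 also turned sign. In FAD4T females of 2 months App went from −0.48 to 0.03 (without wild-type replicate 2), and Prnp from −0.03 to 0.06, being −0.02 and −0.01 without FAD4T replicates 2 and 3 and −0.03 without wild-type replicate 1. In males of 8 months App went from −0.05 to 0.15 (−0.01 without FAD4T replicate 3, −0.05 without wild-type replicate 2) and Thy1 from −0.02 (without FAD4T replicate 1) to 0.80. Prnp there went from −0.04 to 0.12, being −0.01 and −0.02 without FAD4T replicates 1 and 2 and −0.02 and −0.04 without wild-type replicates 1 and 2, and in females of 8 months from −0.08 (without FAD4T replicate 3) to 0.09. For 18 against 2 months Tg went from −0.12 to 0.31 (−0.06 without 2-month replicate 4, −0.12 without 18-month replicate 3) and Per2 from −0.10 to 0.02 (0.02 without 2-month replicate 5, 0.01 without 18-month replicate 3). At 14083958 to 20256049 counts per library, genes under about 3 counts in a group give only bounds or wide ratios.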

Other observations

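In this part the length-matched and young-set tests of the unfolded protein response and clock genes and the correlation without length trends were chosen after the result was seen, and the other tests before.

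Parathyroid markers split the libraries across groups. The mean level of that list was 2.1 to 3.49 in 9 libraries and 6.71 to 9.06 in the other 21. The 9 were FAD4T females of 2 months replicate 1, wild-type females of 2 months replicate 2, FAD4T males of 8 months replicate 3, wild-type males of 8 months replicates 1 and 3, FAD4T females of 8 months replicate 1, wild-type females of 8 months replicate 1, 2-month males of the ageing set replicate 5 and 18-month males replicate 3. Pth, the parathyroid hormone gene, lay between 5.2 and 36000 CPM over the 30 libraries. The first surrogate variable of the 24 libraries took values of 0.246 to 0.324 in the 7 of these libraries it covered and −0.297 to −0.006 in the other 17.

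In the ageing comparison, 4 of 8 Schwann cell markers fell (median log2 fold change −0.51, fry adjusted p = 0.0235, camera adjusted p = 0.0903), and in the oxidative stress response list 8 of 14 fell and 1 rose (median −0.66, fry adjusted p = 0.0247, camera adjusted p = 0.0562). Of 14 C cell and neuroendocrine markers 6 fell (median −0.59, camera adjusted p = 0.0519). Prol1, a secretory protein gene, reached 1550 CPM in 18-month replicate 2.

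The genes that differed between 18 and 2 months were weighed as a pattern. Against a change over all genes shared by 8 months, the log2 fold changes of 18 against 2 and 8 against 2 months in wild-type males, which share no library, had r = −0.03 across 16225 genes, and 0.02 with the length trend of each taken out. Some lists did have medians of the same sign at 8 months: the clock −0.50, the unfolded protein response 0.37 and endothelium −0.56. Others had the opposite sign there: adipocytes 0.73, oxidative phosphorylation 0.32 and ribosomal proteins 0.04. A change shared by the clock, unfolded protein response and endothelial lists was not tested and stays open, and the signs are no evidence of it. A difference between the sets of 2-month libraries may account for part of the calls, since libraries 4 to 6 against 1 to 3, which have the same labels, gave 3328 calls. Gene length bias may account for part too, which is not separate from that difference: fold change followed exonic length with rho = 0.39, but with 0.13 against libraries 1 to 3, and libraries 4 to 6 against 1 to 3 with −0.36. With libraries 4 to 6 as the young group, against genes of matched length the ribosomal protein median went from −1.09 to −0.25 and the oxidative phosphorylation median from −1.06 to −0.35. For the unfolded protein response list both are argued against as the whole cause, since its median relative to genes of matched length was 1.39 times the unmatched 1.02 (17 of 19 members above their matched genes), and 7 of 11 called genes were called with the same sign against libraries 1 to 3, which share the 18-month libraries. For the clock list a difference between the young sets is argued against as the whole cause by 10 of 14 so called. Its matched median, 0.98 times the unmatched, decides nothing on length, since members go both ways, and 5 of 15 lay farther from their matched genes than 95% of all genes do. For both lists a change with age, the hour of dissection and handling of the 18-month set stay open and untested.

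Other splits of the same libraries were run for each count of genes. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For FAD4T against wild type, the real counts were 0, 0, 0 and 4 (males and females of 2 months, males and females of 8 months) and the highest of the other splits gave 0, 6761, 2 and 0, with 10, 10, 10 and 1 splits giving at least the real count, as every split does where that is 0. The split with 6761 calls set FAD4T females of 2 months replicates 1 and 2 with wild-type replicate 1 against the rest, which points to a structure of the samples. In the males of 8 months, taken as paired, splits that part all 3 pairs gave at most 1. For 18 against 2 months the real count was 5840 and the highest other 0, for 8 against 2 months 128 and 0 in males and 47 and 0 in females, and for male against female 14 and 0 at 2 months and 50 and 2 at 8 months, each with 1 split giving at least the real count.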
